A study of Mus musculus with 6 samples.

How the data were processed

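Total RNA of cells that the labels name mouse embryonic hepatoblasts was measured on Affymetrix arrays in 6 samples, 3 that expressed GFP and 3 that expressed an active ATF2 (C2ATF2), all at 8 hours. Per the labels' protocols, cells grew on gelatin in DMEM with serum, HGF, EGF and dexamethasone, RNA was purified on columns, amplified with a whole-transcriptome kit for small RNA amounts, and labelled with biotin. The deposited values are log2 expression values per probe set, made with RMA in Affymetrix Power Tools per the submitters' processing notes. RMA corrects the background of each array, equalises the distributions of the arrays and summarises the probes of a probe set, which compresses small values and makes a shift of all genes in one group invisible. The versions, the probe set level and any later filter or centring are not given in the sources used here. The log2 scale was taken from the use of RMA and from the values, which ran from 0.810 to 12.9, with array medians of 5.56 to 5.6. All 6 columns were used and 0 columns of values were left out.

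The table held 241576 probe sets. Genes were named from the platform's annotation table, which can be old. It named a single gene for 212097 probe sets and several genes for 4475, and the other 25004 are unnamed here. No gene was named from a probe set with several. In a reference table of the mouse assembly GRCm38.p6, 17621 of the 20416 gene symbols were current and 2742 matched as a unique synonym, and the symbols of the annotation were kept, with the current symbol where it differs. No coordinates are given because the sources used here state no genome build. A gene's value was the mean of the log2 values of all probe sets that named only that gene, with a median of 8 probe sets per gene, and 2292 genes had 1 probe set. No dim gene was left out. Values of 3258 probe sets were identical to those of another probe set, which can happen where copies share probes, so that genes with near-identical copies are uncertain.

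Each gene and each probe set was tested with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3) between the groups, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes or all probe sets. The threshold was an adjusted p under 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 42 lists, each with 5 or more measured members. Counts of changed members are those over all genes tested, with counts adjusted over the list alone beside them. The lists, fixed before the data were examined, covered the ATF, CREB and AP-1 family, cAMP and CRE targets, immediate-early genes, MAP kinase phosphatases, the JNK and p38 cascade, p53 targets, apoptosis, stress responses, inflammation and interferon, growth factor ligands, TGF-beta, Wnt, Notch and YAP targets, matrix, epithelial and mesenchymal genes, liver and other cell type markers, the cell cycle, histones, ribosomes, mitochondria, lipid and glucose metabolism, the circadian clock and housekeeping genes. The tests, the naming rule and all but 2 of the alternatives were also fixed then. Named are Atf2, Atf7 and Jun, the 15 genes with the largest rise and the 15 with the largest fall among those past the threshold whose 3 values per group did not overlap, and up to 6 members of each list with the smallest unadjusted p. Genes with predicted gene names, olfactory and vomeronasal receptors and small RNA genes were left out of the ranked part of the rule.

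The table has no detection calls. The background level was therefore set, after the data were seen, per array at the 95th percentile of the values of 1166 olfactory and vomeronasal receptor genes, which few cells outside sensory tissue express. It lay between 4.44 and 4.63, and 62.9% of genes had a mean above it in GFP or C2ATF2. Where all arrays of a group lay at or below it, the change is given as at least N-fold, as the brighter group's mean against, per array of the dimmer group, the higher of the background level and the gene's own value. The fitted log2 change of such a gene is no bound. No fold is given where both groups lay at background.

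The procedure was tested on simulated data with the variances of these arrays and 200 changed items. In the comparison of 20416 genes, 22% of genes changed by 0.5 on the log2 scale were recovered, 66% of those changed by 1, 96% of those changed by 2 and 100% of those changed by 4, with 3 false calls among 145. Among 241576 probe sets, 0% were recovered at changes of 0.5 and 1, 8% at 2 and 62% at 4, with 0 false calls among 35, so that single probe sets showed mainly large changes in this simulation. The 200 changed items were fewer than the genes or probe sets that passed in the data. The adjusted threshold was therefore stricter than in the data, and the shares recovered can be too low. Of 44 simulated lists, the 4 shifted by 0.4 were called and the 40 others were not. The simulated genes varied independently, so this does not test lists of correlated genes, such as ribosome biogenesis (estimated correlation 0.391).

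The alternatives were the replicate number as a block, quantile normalization and median centring, array weights, a variance trend with a robust prior, each array left out, the median of probe sets, the brighter probe sets only, dim genes or probe sets left out, a 2-fold minimum, an adjusted p under 0.10, an equal-variance test without moderation, and for lists an estimated correlation, ranks and fry. Leaving Atf2 out of its list and testing only genes above background were added after the data were seen. Probe sets that name several genes or none entered only the test of probe sets.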

Results

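Gene expression was measured on Affymetrix mouse exon-level arrays in mouse cells that the labels name embryonic hepatoblasts. Hepatoblasts are liver progenitors that can form hepatocytes and bile duct cells. One group of 3 samples expressed green fluorescent protein (GFP) as the control. The other group of 3 samples expressed an active form of the transcription factor ATF2, named C2ATF2 in the labels. Both groups were sampled at 8 hours. The table held 241576 probe sets, of which 212097 named a single gene and were averaged into 20416 genes. Array medians over all probe sets were 5.56, 5.57 and 5.57 on the log2 scale for GFP replicates 1 to 3 and 5.6, 5.58 and 5.58 for C2ATF2 replicates 1 to 3. Across genes, which are not independent replicates, arrays of the same group correlated at 0.988 to 0.993 and arrays of different groups at 0.971 to 0.981. Changes are given as C2ATF2 minus GFP on the log2 scale with the standard error of the fit (SE), with n = 3 arrays in each group. The number of arrays limits the precision. The labels do not say that samples came from separate cultures, so the p-values measure the spread between these samples, which may be technical. By the series title, the comparison addresses which genes are targets of ATF2.

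Atf2, the gene of the expressed factor, was higher in the C2ATF2 samples. Its gene value was 8.02 ± 0.11 (SD, n = 3) in GFP and 9.53 ± 0.12 (SD, n = 3) in C2ATF2, a rise of 1.50 ± 0.11 (SE, adjusted p = 4.53e-05). The rise lay in one stretch of the gene's probe sets. Of 18 Atf2 probe sets, 8 rose, by 2.21 to 4.85, and they stand next to each other in the order of probe set IDs with 1 interruption. The interrupting probe set had a change of 1.50 that did not pass the threshold over all probe sets. The remaining 9 lay outside this stretch, with changes from -0.61 to 0.41 that did not pass. Some of these 9 were bright in GFP, such as 10483738 (mean 10.5, change -0.23) and 10483749 (mean 9.36, change 0.25). They argue against a rise of RNA that spans all the probe sets. The labels do not say which part of ATF2 the construct holds, or from which species. Within the stretch, these values therefore do not separate RNA of the construct from that of the cells' own gene. Atf7, a close relative of Atf2, had a change of -0.34 ± 0.10 (SE, adjusted p = 0.0670), short of the threshold. Jun, a subunit of AP-1 that can dimerise with ATF2, rose by 1.83 ± 0.11 (SE, adjusted p = 9.48e-06).

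**Figure D1:**
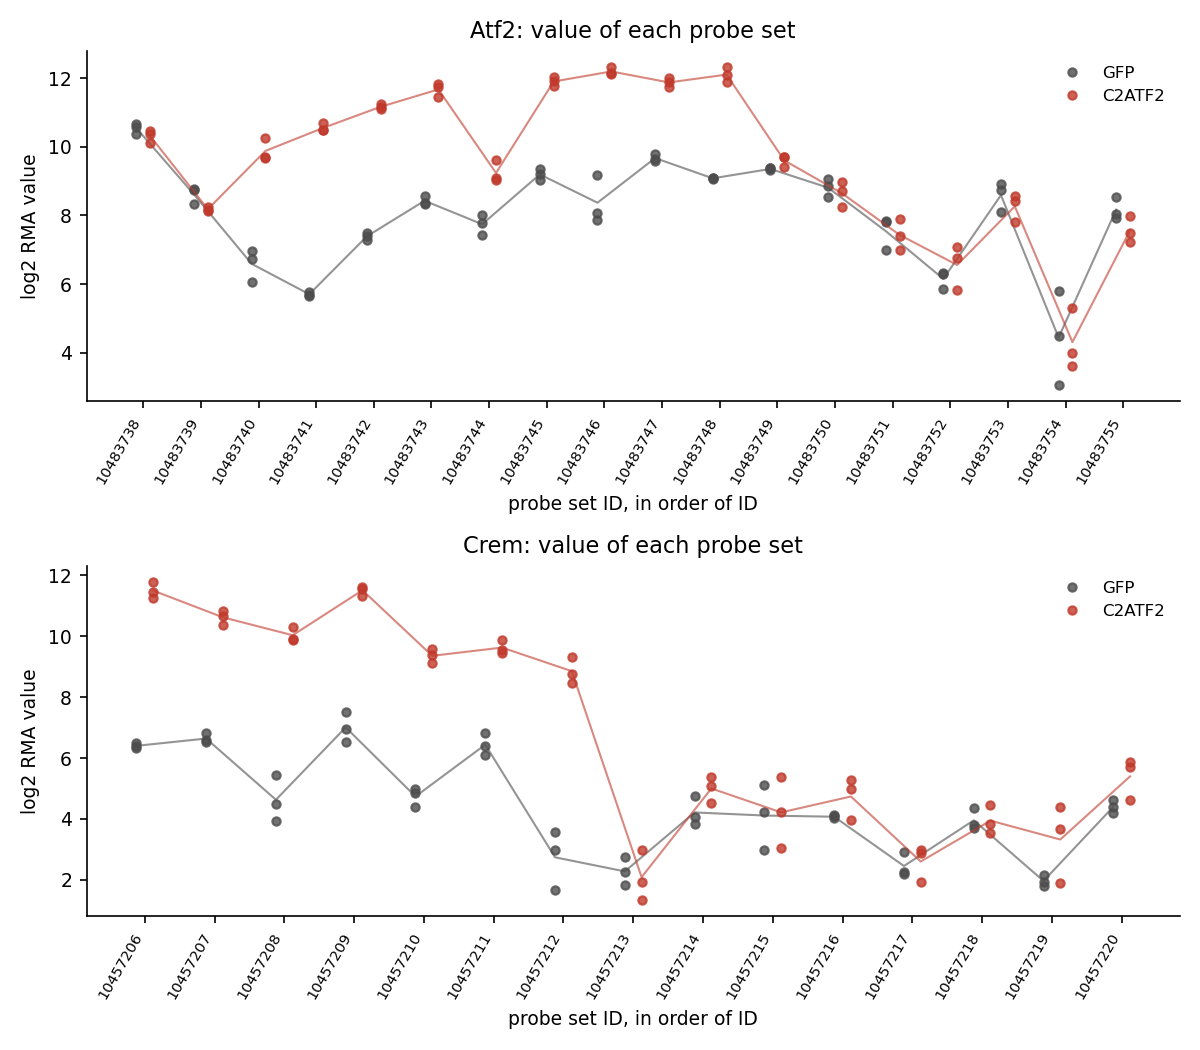
Log2 RMA value (vertical axis) of each probe set of Atf2 (upper panel) and Crem (lower panel), in order of probe set ID (horizontal axis). Points are single arrays, 3 per group, and lines join the group means; 8 of the 18 Atf2 probe sets and 7 of the 15 Crem probe sets passed the threshold, all of them higher in C2ATF2.

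The 15 genes with the largest rises differ in known function. Stmn4, a stathmin that destabilises microtubules, rose by 5.11 ± 0.13 (SE), and Tslp, the cytokine thymic stromal lymphopoietin, by 4.99 ± 0.16 (SE). For both, 2 of the 3 GFP arrays lay above the background level. Nts, the precursor of the peptide neurotensin, lay at background in every GFP array and was at least 14.4-fold higher in C2ATF2. Creb5, a CREB and ATF family member related to Atf2, rose by 4.14 ± 0.13 (SE), or 17.7-fold. Calca, which encodes calcitonin and calcitonin gene-related peptide, rose by 3.60 ± 0.11 (SE). Gzmd, a granzyme, lay at background in GFP and was at least 4.67-fold higher. Tnfaip6, a hyaluronan-binding secreted protein, rose by 3.40, the stress-induced repressor Atf3 by 3.21, the adhesion molecule Mcam by 3.06, and the matrix metalloproteinase Mmp10 by 3.05. Syt11, a synaptotagmin, rose by 2.82, the cation channel Trpc1 by 2.76, and Herc5 (current symbol Herc6), a ubiquitin-like ligase, by 2.68. Tcp11l2 lay at background in GFP and was at least 3.22-fold higher. Pdlim3, an actin-associated LIM protein above background in 2 of the 3 GFP arrays, rose by 2.61. The adjusted p of these 15 genes ranged from 1.51e-07 for Stmn4 to 0.000294 for Pdlim3.

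The falls were smaller. Has2, a hyaluronan synthase, fell by 2.21 ± 0.20 (SE, 4.62-fold lower), and Zfp566, a zinc finger gene, fell by 2.02 ± 0.13 (SE). Myc, the growth-promoting transcription factor, went from 10.2 ± 0.19 (SD) to 8.39 ± 0.18 (SD), a change of -1.82 ± 0.14 (SE, adjusted p = 4.70e-05). Dusp6, a phosphatase of the kinase ERK, changed by -1.72 ± 0.12 (SE). Pcdh18, a protocadherin, changed by -1.61, the LIM homeobox gene Lhx9 by -1.55, the ligand Bmp4 by -1.52, the RNA-binding protein gene Mex3a by -1.48 and Csf1, the macrophage colony-stimulating factor, by -1.48. Jub (current symbol Ajuba), a LIM protein of Hippo signalling, changed by -1.44, the zinc exporter Slc30a1 by -1.43, the kinase Tec by -1.40, Bnc1 by -1.39, the hexokinase Hk2 by -1.36 and Phf15 (current symbol Jade2) by -1.31. The adjusted p of these 15 genes ranged from 1.58e-05 for Zfp566 to 0.00147 for Phf15, for which 2 of the 3 C2ATF2 arrays lay above background. Bnc1 did not pass with the median of its probe sets (adjusted p = 0.0923), and Pdlim3 and Phf15 did not pass in the test without moderated variances (adjusted p = 0.0580 and 0.0765).

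Over all 20416 genes, 2264 passed the threshold, 1299 higher and 965 lower in C2ATF2. The changes of at least 2-fold went mostly upward, 397 genes higher and 80 lower. The largest fall among the genes named here was the 4.62-fold fall of Has2. Of the genes that passed, 232 were left out of the naming rule because they carry predicted gene, receptor or small RNA names, 119 of them higher and 113 lower. Tested one by one, 1766 of the 241576 probe sets passed, 1516 higher and 250 lower. The gene count was 1499 without GFP replicate 1, 1509 without GFP replicate 2 and 1507 without C2ATF2 replicate 3. The probe set count fell much further with 1 array left out, to 111, 204 and 233 without GFP replicates 1 to 3 and to 76, 69 and 154 without C2ATF2 replicates 1 to 3.

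**Figure D2:**
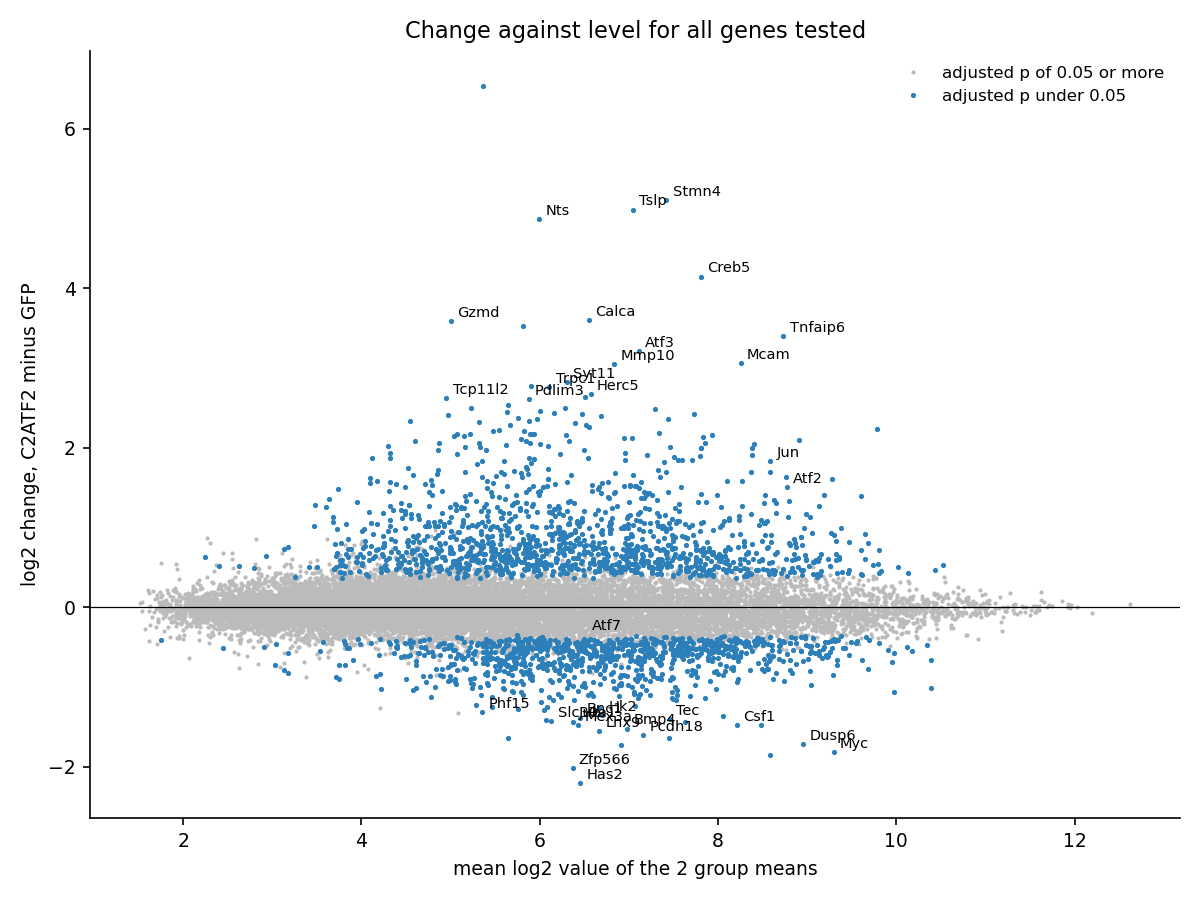
Log2 change, C2ATF2 minus GFP (vertical axis), against the mean of the 2 group means on the log2 scale (horizontal axis) for the 20416 genes. Blue points are the 2264 genes with an adjusted p under 0.05 and grey points the others; gene names mark the genes of the naming rule, from Stmn4 at 5.11 to Has2 at -2.21.

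Members of the ATF, CREB and AP-1 transcription factor family went both ways. Of 32 measured members, 8 rose and 3 fell (9 and 7 adjusted over the list alone, 9 and 9 at an unadjusted p under 0.05). Besides Creb5, Atf3 and Jun, Crem rose by 2.45 ± 0.14 (SE), with 1 of 3 GFP arrays above background, and Fosb by 1.63 ± 0.13 (SE). The list includes Atf2 itself, whose construct was expressed. Its median was -0.01 and its mean 0.44, and camera did not call a shift of the list in one direction (upward, adjusted p = 0.130). Changes that go both ways are not what camera tests. Immediate targets of cAMP and the cAMP response element, the sequence bound by this family, were called upward as a list (camera adjusted p = 0.0230). Of 26 measured, 8 rose and 3 fell (10 and 3 adjusted over the list alone), with a mean of 0.39 and a median of 0.03. With this median, the call rests on part of the members. The camera adjusted p was 0.494 with an estimated correlation between genes, 0.3405 on ranks and 0.0567 with the brighter probe sets only. Nr4a3, an orphan nuclear receptor, was at least 3.41-fold higher, the phosphatase Dusp1 rose by 2.05, the repressor Nfil3 by 1.01, and the coactivator Ppargc1a was at least 1.44-fold higher, both Nr4a3 and Ppargc1a from a GFP level at background. The number that fell was 1 without GFP replicate 2, GFP replicate 3, C2ATF2 replicate 2 or C2ATF2 replicate 3. Crem, Fosb and Dusp1 are also members of other lists.

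Serum-induced immediate-early genes went both ways. Of 26, 7 rose and 5 fell (8 and 7 adjusted over the list alone). A shift of the list in one direction was not called (camera adjusted p = 0.634, upward, with a median of -0.12 and a mean of 0.22). The growth-factor-induced Egr2 rose by 2.36 ± 0.20 (SE), the antiproliferative Btg2 by 1.85, the polo-like kinase Plk3 by 1.52 and Fos by 1.51, while Myc fell, and without C2ATF2 replicate 2 the number that fell was 3. The MAP kinase phosphatases and Sprouty-type feedback inhibitors were also divided. Of 17, 6 rose and 7 fell (6 and 9 adjusted over the list alone). Dusp10 rose by 2.14, Dusp1 by 2.05, Dusp16 by 2.00 and Dusp8 by 1.23. The gene 5530400B01Rik, measured separately but matched as a synonym of Dusp8, rose by 2.46. Dusp6 changed by -1.72 and Spry2, an inhibitor of receptor tyrosine kinase signalling, by -1.10. Camera, which tests only for a shift in one direction, did not call this divided list (adjusted p = 0.753, downward, with a median of -0.28 and a mean of 0.12). The share of its members that changed was larger than that of all genes, where 2264 of 20416 passed. Of 24 genes of the JNK and p38 cascade, whose kinases phosphorylate ATF2, 5 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.338). The JNK scaffold Mapk8ip1 rose by 1.07 and the p38-activated kinase Mapkapk3 by 1.02, and 0 members fell without GFP replicate 3, C2ATF2 replicate 1 or C2ATF2 replicate 3. Mapkapk3 did not pass in the test without moderated variances (adjusted p = 0.0613).

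**Figure D3:**
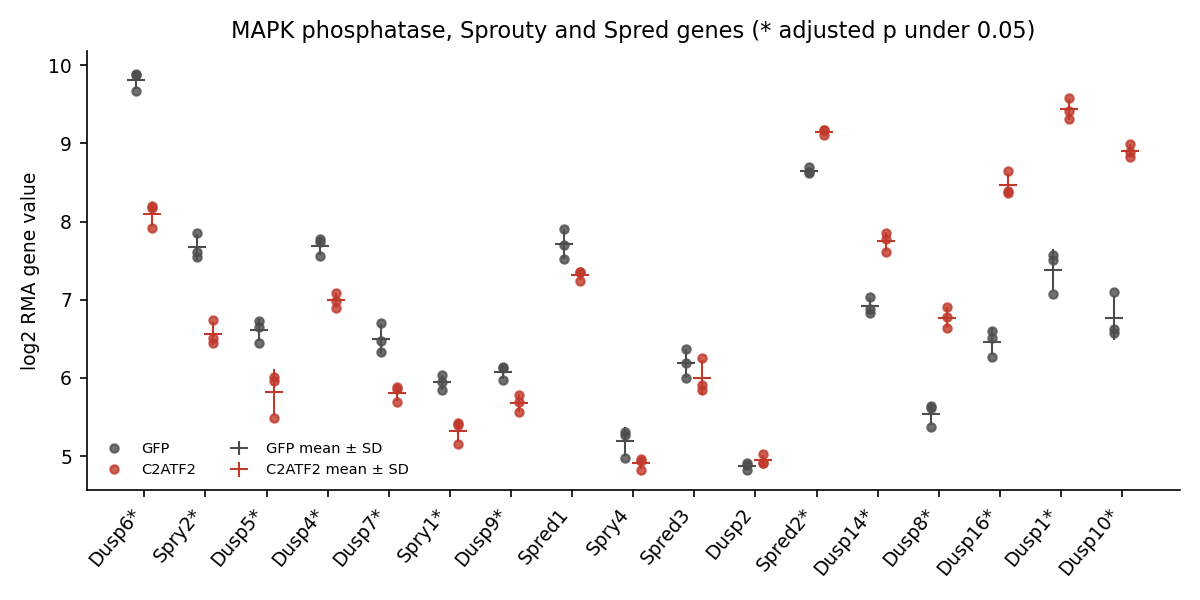
Log2 RMA gene value (vertical axis) of the 17 MAP kinase phosphatase, Sprouty and Spred genes (horizontal axis, ordered by change). Points are single arrays, 3 per group, with the mean and SD of each group, and an asterisk marks an adjusted p under 0.05; Dusp6 at the left changed by -1.72 and Dusp10 at the right by 2.14.

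Part of the genes of ribosome biogenesis fell. In the list of ribosome biogenesis and MYC target genes, 10 of 24 fell and 0 rose (15 and 0 adjusted over the list alone, 15 and 0 at an unadjusted p under 0.05, and 3 and 0 in the test without moderated variances). The median was -0.36. The list stood apart from other genes (camera adjusted p = 2.67e-07), with adjusted p = 0.494 with an estimated correlation. Polr1b, the second largest subunit of RNA polymerase I, changed by -1.27 ± 0.11 (SE), the nucleolar methyltransferase Nop2 by -0.83, the ribosome assembly factor Wdr12 by -0.71 and Polr1c, a subunit of RNA polymerases I and III, by -0.65. Without GFP replicate 1, GFP replicate 2 or C2ATF2 replicate 3, 5 of the 24 passed. Wdr12 did not pass in the test without moderated variances (adjusted p = 0.0504) or with the median of probe sets (adjusted p = 0.142). For the 25 ribosomal protein genes, limma called 0 in either direction, the test without moderated variances 0, and 1 was lower at an unadjusted p under 0.05 (camera adjusted p = 0.634, median -0.02).

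Cell cycle genes fell in part. Among genes of the G2 and M phases, 6 of 27 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.25 and a camera adjusted p of 0.0329 (adjusted p = 0.494 with an estimated correlation). The mitotic kinase Aurka changed by -0.66 ± 0.11 (SE) and the kinetochore protein Cenpf by -0.64, while Prc1, a microtubule bundler of the spindle midzone, rose by 0.59. The number of members that fell was 2 without any one of the GFP replicates, and the list's adjusted p rose to 0.0576 without GFP replicate 2, 0.0889 without GFP replicate 3 and 0.0800 without C2ATF2 replicate 2. Of 29 genes of the G1 and S phases, 4 fell and 0 rose (5 and 0 adjusted over the list alone, 7 and 1 at an unadjusted p under 0.05, 2 and 0 in the test without moderated variances), and the list did not pass (camera adjusted p = 0.0610). The cyclins Ccne1 and Ccne2 changed by -0.97 and -0.89 and their partner kinase Cdk2 by -0.80. Replication-dependent histone genes shifted down (20 measured, 4 fell, 0 rose, 5 and 0 adjusted over the list alone, median -0.25, camera adjusted p = 0.0329). Their adjusted p = 0.494 with an estimated correlation, and it was 0.0789 without GFP replicate 1, 0.0747 without GFP replicate 2 and 0.0796 without C2ATF2 replicate 2. At an unadjusted p under 0.05, 9 histone genes were lower and 0 higher, and 1 was lower in the test without moderated variances. The linker histone gene Hist1h1e (current symbol H1f4) changed by -0.73, 12 of the 20 had a GFP mean above background, and 1 fell without GFP replicate 1, GFP replicate 2, C2ATF2 replicate 2 or C2ATF2 replicate 3. Of the 8 CDK inhibitor genes, Cdkn1a rose by 1.05 ± 0.15 (SE) and 0 fell (1 and 1 adjusted over the list alone, 2 and 3 at an unadjusted p under 0.05, 0 and 1 in the test without moderated variances). That list's median was -0.14, its mean 0.03 and its camera adjusted p 0.783, downward. Cenpf, Cdk2 and Cdkn1a did not pass in the test without moderated variances (adjusted p = 0.0596, 0.0583 and 0.0700), nor Cenpf and Hist1h1e with the median of probe sets (adjusted p = 0.0646 and 0.0755).

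Of 23 p53 target genes, 5 rose and 1 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.273). The proapoptotic Pmaip1 rose by 2.12 ± 0.18 (SE), Btg2 by 1.85 and the stress-induced Gadd45a by 1.04, while the kinase Plk2 changed by -1.07, and 2 members fell without GFP replicate 1 or C2ATF2 replicate 3. Among 22 apoptosis regulators, 1 rose and 4 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.295). The antiapoptotic Bcl2 rose by 1.19, and the antiapoptotic Bcl2l1 changed by -0.98, and the number that fell was 2 without GFP replicate 1, GFP replicate 3, C2ATF2 replicate 1 or C2ATF2 replicate 3. Genes of the ATF4 integrated stress response moved little: 2 of 32 rose and 1 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.634). Myd116 (current symbol Ppp1r15a), which directs dephosphorylation of eIF2alpha, rose by 1.46, and the member that fell, Chac1 (-0.50), passed with C2ATF2 replicate 2 left out but with no other single array left out. In the unfolded protein response list of 24 genes, limma called 0 in either direction, the test without moderated variances called 0, and 1 was lower at an unadjusted p under 0.05 (camera adjusted p = 0.671). Of 16 heat shock genes, 3 rose and 0 fell (3 and 1 adjusted over the list alone, 4 and 3 at an unadjusted p under 0.05, 2 and 1 in the test without moderated variances). The small chaperone Hspb8 rose by 1.63 and Hspa4l by 1.09, and the list had a median of -0.11, a mean of 0.18 and a camera adjusted p of 0.901, upward. Gadd45a, Myd116 and Chac1 did not pass in the test without moderated variances (adjusted p = 0.0520, 0.0610 and 0.191), nor Gadd45a and Chac1 with the median of probe sets (adjusted p = 0.118 and 0.296).

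Matrix proteases and their inhibitors shifted upward (28 measured, 7 rose, 1 fell, 8 and 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.00536). The adjusted p was 0.494 with an estimated correlation. Besides Mmp10, the plasminogen activator inhibitor Serpinb2 rose by 2.23 ± 0.12 (SE), tissue plasminogen activator Plat by 1.97 ± 0.11 (SE), and the metalloproteinases Adam8 by 1.14 and Adamts1 by 1.05. The 1 member that fell did not pass with any single array left out. Among 30 extracellular matrix and adhesion genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.671). The collagen Col12a1 rose by 0.78 and the matrix glycoprotein Thbs1 changed by -1.01. TGF-beta response genes went both ways (23 measured, 6 rose, 7 fell, 6 and 9 adjusted over the list alone, camera adjusted p = 0.634). The ligand Tgfb3 rose by 1.06 and the activin subunit Inhba by 0.92, and the BMP target Id1 changed by -1.01. Of 20 EMT transcription factors and mesenchymal genes, 3 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.476). The EMT regulators Snai2 and Zeb2 rose by 0.75 and 0.76, and 0 members fell without any one of the GFP replicates or C2ATF2 replicate 3. Of 22 YAP and TEAD targets, 3 rose and 7 fell (3 and 11 adjusted over the list alone, median -0.25, camera adjusted p = 0.0879). Amotl2 changed by -1.05 and Asap1 by -0.68, and without C2ATF2 replicate 1 the number that fell was 3. Of 24 cytoskeleton and SRF target genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.671), with the actin-binding Cnn1 higher by 0.97, and without C2ATF2 replicate 2 the number that fell was 0. Snai2, Zeb2, Amotl2 and Cnn1 did not pass in the test without moderated variances (adjusted p = 0.0533, 0.0600, 0.0715 and 0.0799).

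**Figure D4:**
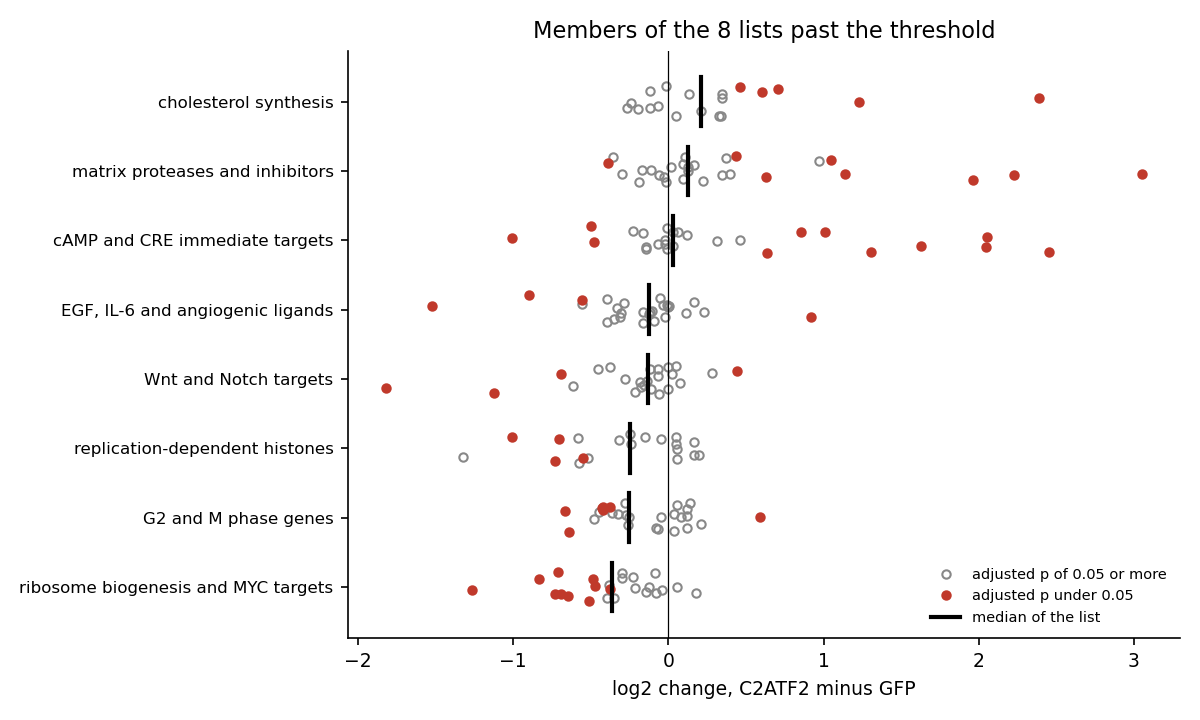
Log2 change, C2ATF2 minus GFP (horizontal axis), of each measured member of the 8 gene lists that passed the camera threshold (vertical axis, ordered by median). Filled points are members with an adjusted p under 0.05, open points the others, and bars the list medians, from -0.36 for ribosome biogenesis and MYC targets to 0.21 for cholesterol synthesis.

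A few growth factor ligands fell, and their list was called downward. In this list, of EGF, IL-6 and angiogenic ligands, 3 of 27 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.12 and a camera adjusted p of 0.0329 (adjusted p = 0.494 with an estimated correlation). Bmp4 changed by -1.52 and Hbegf, a ligand of the EGF receptor, by -0.90 ± 0.12 (SE), while Inhba rose. The list's adjusted p was 0.0747 without GFP replicate 2, 0.0796 without C2ATF2 replicate 2 and 0.0628 without C2ATF2 replicate 3, 0.191 with the brighter probe sets only and 0.0998 on ranks. Wnt and Notch targets shifted downward (24 measured, 3 fell, 1 rose, 4 and 1 adjusted over the list alone, median -0.13, camera adjusted p = 0.0408). Their adjusted p was 0.494 with an estimated correlation, 0.0762 without GFP replicate 1 and 0.0953 without C2ATF2 replicate 3. Counts of members without single arrays were as low as 2 for falls, without GFP replicate 1, GFP replicate 2 or C2ATF2 replicate 3. The members that fell were Myc, the Notch ligand Jag1, which changed by -0.69, and the Notch target Hes1, which changed by -1.13. Hes1 did not pass without GFP replicate 1, GFP replicate 2 or C2ATF2 replicate 3 (adjusted p = 0.0658, 0.0622 and 0.0598), nor in the test without moderated variances (adjusted p = 0.198). The member that rose, Lgr5, lay at background in both groups and passed with GFP replicate 3 left out but with no other single array left out.

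Inflammatory genes did not move in one direction. Of 32 NF-kB and inflammatory genes, 5 rose and 5 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.901, downward, with a median of -0.001 and a mean of 0.02). The NF-kB subunit Rel rose by 1.69 ± 0.13 (SE), Csf1 fell, and the adhesion molecule Vcam1 changed by -0.86. The number that rose was 2 without GFP replicate 1, GFP replicate 3 or C2ATF2 replicate 3 and 3 without any one of the others. Of 30 type I interferon response genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone, 7 and 3 at an unadjusted p under 0.05, 0 and 0 in the test without moderated variances). A shift of the list in one direction was not called (camera adjusted p = 0.318), and 10 of the 30 had a GFP mean above background. The ubiquitin-like modifier Isg15 rose by 2.28 ± 0.29 (SE), the RNA sensor Ifih1 by 1.70 and the chemokine Cxcl10 by 1.55. Of the GFP arrays, 1 lay above background for Isg15 and 2 for Cxcl10. Among 22 cytokine signalling suppressors and STAT3 targets, 4 fell and 0 rose (7 and 1 adjusted over the list alone, 8 and 2 at an unadjusted p under 0.05, 1 and 0 in the test without moderated variances). This list did not pass (camera adjusted p = 0.0610). The receptor genes Osmr and Lifr changed by -0.78 and -0.73, and 2 members fell without GFP replicate 2, GFP replicate 3, C2ATF2 replicate 2 or C2ATF2 replicate 3. Without GFP replicate 3, 3 members rose. Vcam1, Isg15, Ifih1, Cxcl10, Osmr and Lifr did not pass in the test without moderated variances (adjusted p = 0.106, 0.0780, 0.0824, 0.110, 0.0546 and 0.0838), nor Osmr and Lifr with the median of probe sets (adjusted p = 0.0923 and 0.0529).

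Cholesterol synthesis genes shifted upward (19 measured, 5 rose, 0 fell, 6 and 0 adjusted over the list alone, 9 and 0 at an unadjusted p under 0.05, 2 and 0 in the test without moderated variances). The median was 0.21 and the camera adjusted p 0.0221 (adjusted p = 0.494 with an estimated correlation). Phosphomevalonate kinase (Pmvk) rose by 2.39 ± 0.13 (SE), the reductase Dhcr7 by 1.23 ± 0.14 (SE) and the isomerase Idi1 by 0.71. Of 21 fatty acid synthesis and lipid storage genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.693, upward, with a median of -0.03 and a mean of 0.08). Dgat1, an enzyme of triglyceride synthesis, rose by 1.47, the elongase Elovl5 by 1.00, and fatty acid synthase (Fasn) changed by -0.61. In the hypoxia and glycolysis list, 2 of 27 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.338). Ndrg1 rose by 1.02 and Hk2 changed by -1.36. Of 23 NRF2 targets, 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.634). Their median of 0.006 became -0.008 after quantile normalization and -0.010 after centring. The glutathione transferase Gstm1 rose by 1.09 and catalase (Cat) by 1.06, while Gclc, which makes glutathione, changed by -0.92, and 1 member fell without GFP replicate 2, GFP replicate 3, C2ATF2 replicate 1 or C2ATF2 replicate 3. In the respiratory chain list of 27 genes, limma called 0 in either direction, the test without moderated variances called 0, and 1 was higher at an unadjusted p under 0.05 (camera adjusted p = 0.338). Of 18 circadian clock genes, 5 rose and 2 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.284). Hlf rose by 1.21 and Nfil3 by 1.01, and the repressor Nr1d1 changed by -0.83. Of 17 housekeeping genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone, 4 and 0 at an unadjusted p under 0.05, 1 and 0 in the test without moderated variances, camera adjusted p = 0.252). Polr2a, the largest subunit of RNA polymerase II, rose by 0.78 and was the member that passed whichever array was left out. Idi1, Dgat1 and Gclc did not pass in the test without moderated variances (adjusted p = 0.0786, 0.0600 and 0.0515), nor Fasn with the median of probe sets (adjusted p = 0.117).

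Genes of liver cell identity changed little, and many of them lay at background. Of 33 hepatoblast and hepatocyte genes, 16 had a GFP mean above background, 1 fell and 0 rose (1 and 0 adjusted over the list alone, 3 and 2 at an unadjusted p under 0.05, 0 and 0 in the test without moderated variances). The list's camera adjusted p was 0.793, downward, with a median of 0.02 and a mean of -0.02. The bile acid receptor Nr1h4 changed by -0.74 ± 0.13 (SE), 1 member rose without C2ATF2 replicate 1, and 2 fell without GFP replicate 2. Of 27 mature hepatocyte genes, 6 had a GFP mean above background, and 2 rose and 0 fell (2 and 0 adjusted over the list alone, 3 and 1 at an unadjusted p under 0.05, 0 and 0 in the test without moderated variances, camera adjusted p = 0.634). Their median was 0.02, and -0.003 after quantile normalization. One of the members that rose, Ass1, lay at background in both groups, and it was the only one to rise without GFP replicate 1, C2ATF2 replicate 2 or C2ATF2 replicate 3. Biliary and progenitor genes included large changes (23 measured, 5 rose, 2 fell, 5 and 2 adjusted over the list alone, median 0.02, camera adjusted p = 0.231). The chloride channel Cftr, at background in GFP, was at least 4.21-fold higher, the secreted protein osteopontin (Spp1) rose by 1.87 ± 0.15 (SE) and the lipopolysaccharide coreceptor Cd14 by 2.16 ± 0.22 (SE). Without C2ATF2 replicate 2, 3 members of this list rose, and Krt19, with a change of 0.64, was among those lost (adjusted p = 0.0639). Among 27 epithelial junction and keratin genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.634). The member that rose was Krt19, so that without C2ATF2 replicate 2 the count was 0, and 1 fell without GFP replicate 2, GFP replicate 3, C2ATF2 replicate 2 or C2ATF2 replicate 3. Nr1h4, Ass1, Cd14 and Krt19 did not pass in the test without moderated variances (adjusted p = 0.0719, 0.124, 0.0501 and 0.129), nor Krt19 with the median of probe sets (adjusted p = 0.133).

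Markers of other cells that a fetal liver culture can hold showed few changes. Of 23 stellate cell and fibroblast markers, 1 rose and 0 fell (0 and 0 adjusted over the list alone, 3 and 3 at an unadjusted p under 0.05, 0 and 0 in the test without moderated variances, camera adjusted p = 0.629). That member, desmin (Des), passed only without GFP replicate 3 when single arrays were left out, and 1 member fell without GFP replicate 1. Des did not pass with the arrays centred (adjusted p = 0.0515) or with the median of probe sets (adjusted p = 0.0573). Of the 23 endothelial markers, 7 had a GFP mean above background, so most could hardly show a fall. For this list, limma called 0 in either direction and the test without moderated variances called 0, and 3 were higher at an unadjusted p under 0.05 (camera adjusted p = 0.338, fry adjusted p = 0.0176, upward, median 0.06). Of 21 macrophage and leukocyte markers, 6 had a GFP mean above background, and 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.925, upward, with a median of -0.03 and a mean of 0.10). The members that rose were Cd14, which the biliary list also holds, and the lysosomal Cd68, which rose by 1.03 ± 0.13 (SE), and 0 fell without GFP replicate 1, GFP replicate 2 or C2ATF2 replicate 2. Cd14 did not pass in the test without moderated variances (adjusted p = 0.0501). Of the 18 erythroid and megakaryocyte markers, 10 had a GFP mean above background. Among the 18, limma and the test without moderated variances called 0 in either direction, and 0 passed at an unadjusted p under 0.05 (camera adjusted p = 0.823).

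Of the 42 lists, 8 passed the camera threshold, 3 upward and 5 downward. With an estimated correlation between genes 0 passed, 3 lists had an unadjusted camera p under 0.05, and the smallest was 0.0146. That setting has few residual degrees of freedom, so it cannot decide whether correlation accounts for the calls. Among the lists called, matrix proteases (-0.023), cholesterol synthesis (-0.018) and growth factor ligands (0.0015) had estimated correlations below the preset 0.01. The others called had estimates above it. The ribosome biogenesis list was the one that also passed on ranks. The self-contained test fry, which asks only whether the genes of a list move on balance in one direction, called 15 lists, 10 upward and 5 downward, among them all 8. The others, all upward, were the biliary (fry adjusted p = 0.000859), ATF, CREB and AP-1 (0.00269), circadian (0.00269) and JNK and p38 (0.00634) lists. They also included the endothelial (0.0176), p53 (0.0184) and EMT (0.0370) lists. With only the brighter probe sets of each gene, 3 lists passed, and with 1 array left out the number of lists was as low as 5, without GFP replicate 2 or without C2ATF2 replicate 2.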

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

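The values in this part were looked up after the results were seen. Probe sets without a gene name in the annotation and probe sets that name several genes stood outside the gene comparison. Of 25004 unnamed probe sets, 115 passed the threshold, 93 higher and 22 lower in C2ATF2. The probe sets 10365843 and 10365841 had means of 3.34 and 3.17 in GFP, below the probe set background of 5.04, and rose to 7.63 and 6.94 in C2ATF2. The probe set 10339886 fell from 6.13 to 3.48, below that background. Of 4475 probe sets that name several genes, 49 passed, 46 higher and 3 lower. Of the 4475, 21 also carry the name of the predicted gene Gm6460, and 20 of them passed, all higher. The 21 hold 17 distinct sets of values. The predicted gene itself, measured by 2 probe sets with identical values, had a mean of 2.10 in GFP, below the probe set background, and of 8.64 in C2ATF2. Which of the genes that share these probe sets rose was not analysed here.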

How the results depend on the processing

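Most alternatives were fixed before the data were examined, and leaving Atf2 out of its list and testing only genes above background were chosen after. The number of genes past the threshold was 2264. It moved by over 1.5 times with the median of probe sets (1170, of which 1078 were shared) and with a 2-fold minimum (477). The same held in the equal-variance test without moderation (803, of which 728 were shared). With each array left out it was 1499 to 1811, the highest without C2ATF2 replicate 1. It also moved by over 1.5 times, narrowly, without GFP replicate 1 (1499), GFP replicate 2 (1509) or C2ATF2 replicate 3 (1507). The number of probe sets was 1766, 4959 with a variance trend and robust prior, 4819 with dim probe sets left out, and 69 to 233 with each array left out (69 without C2ATF2 replicate 2, 233 without GFP replicate 3). The number of lists was 8, 3 with the brighter probe sets only, 0 with an estimated correlation between genes, 1 on ranks, 15 with fry, and 5 to 10 with each array left out (5 without GFP replicate 2, 10 without C2ATF2 replicate 1). Scaling moved the share of higher genes from 57.4% to 54.6% with quantile normalization and 54.1% with centring. Atf2 rose in every alternative, by 1.43 to 1.60. Over the 183 named genes, 2596 of 2913 values kept their call, 312 lost the threshold, 3 gained it (Atf7, with the brighter probe sets only, dim genes left out or genes above background only), and 2 turned: Pim3 was 0.44 with the median of probe sets and Gzmb -0.0939 with the brighter probe sets only. Over the 8 lists, 104 of 136 values kept their call and 32 lost it. The cause was not tested.

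The groups share replicate numbers. The labels do not say that a number marks a shared culture or day, so the test was fixed beforehand as unpaired. Deviations from the group mean correlated, for the same number, at 0.0894, -0.0482 and 0.144, and not every array was closest to its own number. With the replicate block, 2060 genes passed, of which 1924 were shared, and 8 lists, and 0 probe sets passed in limma (smallest adjusted p = 0.0851, with 2 residual degrees of freedom), against 29843 at an unadjusted p under 0.05.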

Other observations

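The gene groups and explanations in this part were chosen after the results were seen, except the tests of small RNA recovery and of the split of the samples, which were set before their values were seen. Genes of hyaluronan metabolism were looked up because of Has2, and no list of them was tested. Besides the fall of the synthase Has2, the hyaluronidase gene 9930013L23Rik (current symbol Cemip) fell by 1.64 and Hyal2 by 0.64, while the synthase Has1 rose by 1.01 and the hyaluronan-binding Tnfaip6 by 3.40. Has1 did not pass in the test without moderated variances (adjusted p = 0.0524). The receptors Cd44 (0.21) and Hmmr (0.17) and the proteoglycan Vcan (-0.22) did not pass, and Has3 and Hyal1 lay at background in both groups. Of the 6 Armcx genes, which encode armadillo repeat proteins and lie together on the X chromosome, 5 rose, by 2.42 for Armcx4, 1.70 for Armcx3, 1.18 for Armcx5, 1.18 for Armcx1 and 0.59 for Armcx6, and Armcx2 had -0.39 (adjusted p = 0.0530). Armcx6, with 1 of 3 GFP arrays above background, did not pass without C2ATF2 replicate 2 (adjusted p = 0.0582) or with the brighter probe sets only (adjusted p = 0.124), and neither it nor Armcx5 passed in the test without moderated variances (3 and 0 of the 6). Of 10 granzyme genes, Gzmd, Gzme (1.35) and Gzmb rose and 0 fell (limma; 3 and 0 at an unadjusted p under 0.05, 1 and 0 in the test without moderated variances). Gzmb lay at background in GFP and was at least 1.30-fold higher. With the brighter probe sets only, Gzmb had -0.0939 (adjusted p = 0.837) and Gzme 0.91 (adjusted p = 0.131), so neither passed. Of 27 RNA polymerase subunit genes, 1 rose and 6 fell (1 and 6 in the test without moderated variances), and of 38 Hox genes 2 rose and 6 fell (0 and 2 in that test).

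The liver genes Alb (3.54 in GFP and 3.66 in C2ATF2), Afp (3.60 and 3.86) and Ttr (4.35 and 4.33) lay at background in both groups. The keratins Krt8 (9.59 and 9.38) and Krt18 (8.83 and 8.50) and the filament gene Vim (10.9 and 10.8) lay well above it. So did the mesothelial genes Msln (9.18 and 8.82), Upk3b (8.02 and 8.21) and Wt1 (7.30 and 7.60). Alb, Afp and Ttr are markers of hepatoblasts, so these values question the name that the labels give the cells, whose identity was not tested here.

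Of 37 small nucleolar RNA genes (Snora and Snord), a group chosen after the results were seen, 18 fell and 0 rose (limma; 22 and 1 at an unadjusted p under 0.05, 1 and 0 in the test without moderated variances). A lower recovery of small RNAs in the C2ATF2 samples could account for this. As a uniform loss it would give all 29 genes above background the same change only if their probe sets responded alike. Their changes, with a median of -0.79, ran from -1.73 to 0.27 and differed by more than their errors (Cochran Q, approximate, n = 29 genes, p = 2.6e-52). These errors hold only the spread between arrays, not differences in response between probe sets, so the test cannot decide. The 15 brighter of these genes also differed, a test added after the result was seen because RMA compresses small values (n = 15 genes, p = 3.72e-28), where Snord82 (GFP mean 8.74) changed by -1.37 ± 0.18 (SE) and Snord49b (GFP mean 8.65) had -0.03 ± 0.20 (SE). That test has the same limit. A uniform loss, one that differs between RNAs and one shared with other small RNAs were all left open. The 9 genes grouped as other small RNAs had a median of -0.0568, and 3 of them fell, Rnu2 by 0.90, Scarna8 by 0.86 and Rnu73a by 0.70. This group is not a separate one, since Rnu73a and Rnu3a (0.21) are themselves small nucleolar RNAs.

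RNA of the expressed construct might bind probe sets of the related gene Creb5. Against this, 11 of the 12 Creb5 probe sets passed the threshold, and all 12 were higher in each C2ATF2 array than in each GFP array. The 1 that did not pass, 10538339, changed by 0.68 (limma adjusted p = 0.257). Of the 13 probe sets of Atf7, also a relative of Atf2, 0 rose. For Crem, 7 of 15 probe sets rose, by 3.19 to 5.10 in the 4 with a GFP mean above the probe set background of 5.04. The other 3 that rose had a GFP mean below it, so in these 3 a low GFP level did not hide a rise. The 8 that did not pass had a mean of 3.91 in C2ATF2, and these values cannot tell probe sets that respond poorly from a part of the gene that did not rise.

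A hypothesis is that the MAP kinase phosphatases moved by the kinase they act on. Those known to act mainly on JNK and p38 (Dusp1, Dusp8, Dusp10 and Dusp16) had a mean change of 1.85 ± 0.42 (SD over genes) and those known to act mainly on ERK (Dusp5, Dusp6, Dusp7 and Dusp9) a mean of -0.90 ± 0.57 (SD over genes). The difference of 2.75 had an exact permutation p of 0.0286, the smallest that 70 regroupings of 8 genes allow. The grouping was made after the changes were seen, related genes are not independent, and Dusp2 (0.08), Dusp4 (-0.70), Dusp14 (0.83) and the separately measured Dusp8 synonym 5530400B01Rik (2.46) were in neither group, so the p rests on chosen genes and a test in other samples is needed.

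The 6 samples can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split was the 1 split with a count as large for genes (2264, highest other 0), for probe sets (1766, highest other 0) and for lists (8, highest other 6, the split that joins GFP replicates 1 and 2 with C2ATF2 replicate 1). Every other split mixes GFP and C2ATF2 arrays, so a difference between the groups adds to the spread within its sets and lowers its counts. The counts of the other splits therefore do not measure what chance alone would give. In limma at an unadjusted p under 0.05, other splits gave up to 1173 genes and 16408 probe sets, and the real split gave 4618 and 30127.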
